A study of Mus musculus with 6 samples.

How the data were processed

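Kidney RNA of 6 samples was measured on single-colour Agilent mouse arrays labelled with Cy3. Per the labels, total RNA was checked for integrity, purified, amplified and labelled before hybridisation, with the mouse as the organism and kidney as the tissue. The scanner files hold intensity values per spot, which per the file headers were read with Feature Extraction 10.7.1.1 for slide 1 and 10.7.3.1 for slide 2, protocol GE1_107_Sep09, with probe positions in mm9. The intensity column used for all results is the processed signal that the deposited scanner files give. The authors' deposited series values were set against the scanner signals of each array: their medians were 6.07 to 6.09 and Spearman's rho was at least 0.999, so they were read as log2 values, with their exact normalization unknown. Their scale and direction follow from this match, and the submitters' processing notes name limma without a version. The well above background, saturation and outlier columns of the scanner files are flags of the file, other than intensity, as deposited.

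Signals were set to log2 of the processed signal minus the 75th percentile of each array. Control spots were left out (43379 of 45018 spots were used), as were spots marked non-uniform or as population outliers, and spots of a probe were averaged. Of 41174 probes 27668 were named through their accession and 6060 through symbol or synonym in the table of RefSeq genes, and 7446 kept the name of the file, which can be old. A gene took its probe with the highest mean over the arrays, and genes well above background on at least 2 of 6 arrays were tested, 19615 in all (9 with a missing value on some array). Of 5659 genes with several probes above background on all 6 arrays, 100 had probes over 1 log2 unit apart in the wild-type injury change and 0 had probes at least 2-fold in opposite directions. Where a probe was not well above background on every array of a group, the change is given as a bound, "at least N-fold": the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Of the genes given with a log2 change, Chrdl1, Ciart, Pvalb, Nkg7, Sema3a and Tagln3 were well above background on 1 of the 2 wild-type injured arrays, and Hk2, Tpx2, Fosl1, Saa2, Camp and Cdk1 on 1 of the 2 wild-type sham arrays.

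Tests used limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8), and are two-sided. Group means were fitted to all 6 arrays with 1 shared spread per gene (2 residual degrees of freedom), because each Gpr97-deficient group has 1 array, which is assumed to vary like the wild-type arrays. Genotype over both surgeries came from an additive model of genotype and surgery (3 residual degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Before the data were examined, 39 gene lists were fixed, and the 38 lists with at least 3 measured members were tested with camera at an inter-gene correlation of 0.01 and with an estimated correlation, adjusted over lists within each of 6 comparisons. Of 699 list members 691 had a probe and 655 were tested. The word "adjusted over the list alone" means that Benjamini-Hochberg ran over the members of 1 list.

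The rule for named genes, also fixed before the data were examined, took Adgrg3 and the Sema3A axis in every comparison, and the genes with the largest changes past the threshold. Where none passed it took the 3 genes with the largest moderated t each way, with predicted and accession-named genes left out. For each list it took up to 4 members past the threshold adjusted over the list alone, or else the 2 with the largest absolute change. Some genes that this rule takes are not reported here. Marker lists served as gene lists on whole tissue, not to name cells.

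No 2 of the 6 arrays held identical signals (0 of 15 pairs), and Pearson's r across genes lay between 0.938 and 0.98. The first 2 principal components held 40.9% and 27.2% of the variance. Between the 2 wild-type sham arrays 2901 genes differed over 2-fold, and between the 2 wild-type injured arrays 3419. Slide, which follows the scan, was tested as a batch: both slides hold wild-type sham and injured arrays, and the Gpr97-deficient arrays are on slide 2 only, so results were repeated with slide as a block and within slides.

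The fits were tested on simulated data made from the wild-type injury comparison with 19606 genes and 50 changed genes per size. Limma called 0 at a log2 change of 1, 6 at 2, 38 at 4 and 48 at 6, with 5 false calls, and 4.74% of unchanged genes had an unadjusted p under 0.05. Camera called 3 of 3 shifted lists and 0 unshifted lists with the preset correlation, and 0 of 3 shifted lists with an estimated correlation. The latter setting missed every simulated shift, all of a log2 change of 1, so failing it does not argue against a list with a shift of that size. Smaller and larger list shifts were not simulated with either setting. The simulated genes were drawn independently, so false list calls among genes that vary together were not tested. In the data the estimated correlation was 0.96 for red blood cell markers and 0.69 for the respiratory chain. P-values with the preset 0.01 can therefore be too low.

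Alternatives tried were quantile normalization, normexp (offset 50) on the mean and background intensities, the deposited log2 values, no filter on dim probes, probes above background on all 6 arrays, the mean of the probes of a gene, outlier spots kept, a variance trend and robust prior, an added 2-fold threshold, the additive model, the wild-type arrays alone, slide as a block and leaving out each array. Mapping, pathway databases and clinical data were not analysed here.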

Results

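RNA from mouse kidney was measured on 6 single-colour arrays. The labels put 2 arrays in the group of wild-type mice after sham surgery and 2 in the group of wild-type mice after renal ischaemia/reperfusion injury, in which the blood supply of the kidney is interrupted and restored. Mice deficient in Gpr97, the older name of the adhesion G protein-coupled receptor gene Adgrg3, gave 1 array after sham surgery and 1 after injury. The duration of ischaemia and the time of collection are not given in the sources used here. The labels do not say that the arrays of a group come from separate animals, so the limma p-values measure only the spread between these samples, and part of it may be technical. Camera p-values compare the genes of a list with the other genes. They do not measure the spread between Gpr97-deficient samples, which have 1 array per group, and a very low one can come from 1 array. Each array carried 41174 probes, of which 63.0% (wild-type injured array 2) to 71.1% (wild-type sham array 2) were well above background, and 0 spots were saturated. Wild-type sham array 1 and wild-type injured array 2 were on slide 1, and the other 4 arrays were on slide 2. The 2 arrays of each wild-type group thus lay on different slides. In the fit of group means, their spread cannot be told apart from a slide difference. All signals are on a log2 scale, relative to the 75th percentile of the array, and the number of arrays limits their precision. The samples are labelled male, but on wild-type injured array 1 all 4 Y-linked genes were not well above background. On the same array the brightest probe of Xist, the RNA that silences an X chromosome in female cells, stood at 4.10, against -5.38 or lower on the other 5 arrays. These values argue against the same animal behind both wild-type injured arrays. For the wild-type sham arrays the question stays open.

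**Figure D1:**
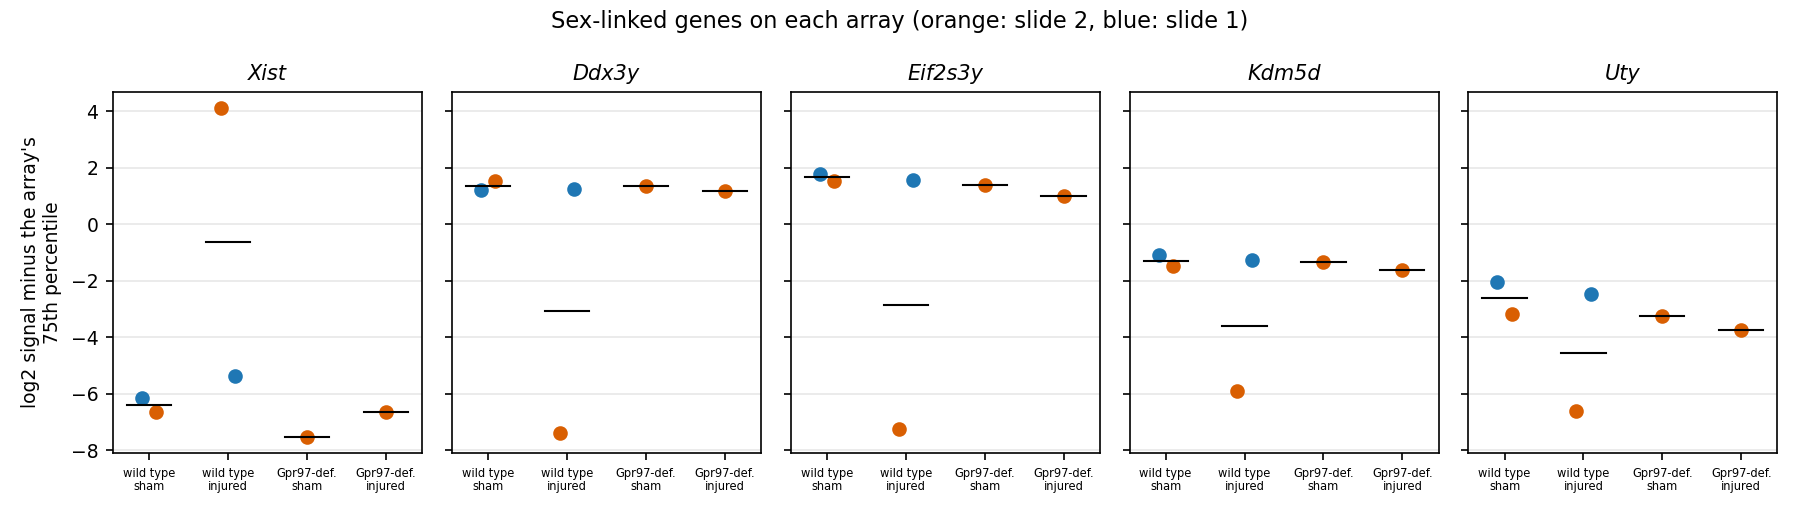
Signal of Xist and 4 Y-linked genes on each array, as log2 signal minus the 75th percentile of the array (vertical axis), by group; each point is 1 array, blue for slide 1 and orange for slide 2, and lines are group means. Wild-type injured array 1 has Xist at 4.10 and Ddx3y at -7.39, against -5.38 or lower and 1.19 or higher on the other 5 arrays.

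Adgrg3 (NM_173036, probe A_51_P247694, chromosome 8, 97568989 to 97569048 in mm9) was examined first, because it checks the genotype labels. Its signal was 0.15 ± 0.13 (SD, n = 2) in wild-type sham kidneys and 1.18 ± 0.11 (SD, n = 2) in wild-type injured kidneys. It was -5.34 on the Gpr97-deficient sham array and -5.71 on the Gpr97-deficient injured array, where the probe was not well above background. Adgrg3 differed by -5.49 (SE 0.30) between genotypes after sham surgery, and it was at least 118-fold lower in the Gpr97-deficient kidney after injury. With limma, as for all other genes in the main model, the adjusted p of Adgrg3 was above 0.05, at 0.773 after sham surgery and 0.305 after injury. Over both surgeries its adjusted p was 0.201, and with a variance trend and robust prior Adgrg3 passed after injury (adjusted p 0.0449) and over both surgeries (adjusted p 0.0339). A second Adgrg3 probe was well above background on 2 of 6 arrays, both of them wild-type injured. Which part of Adgrg3 was removed is not given in the sources used here. Whichever part it was, the first probe was far lower on both Gpr97-deficient arrays than on every wild-type array (0.05 or higher). Its values argue against exchanged genotype labels. In wild-type kidneys Adgrg3 was 1.03 higher after injury (SE 0.24, adjusted p 0.772), by 1.01 on slide 1 and 1.05 on slide 2.

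**Figure D2:**
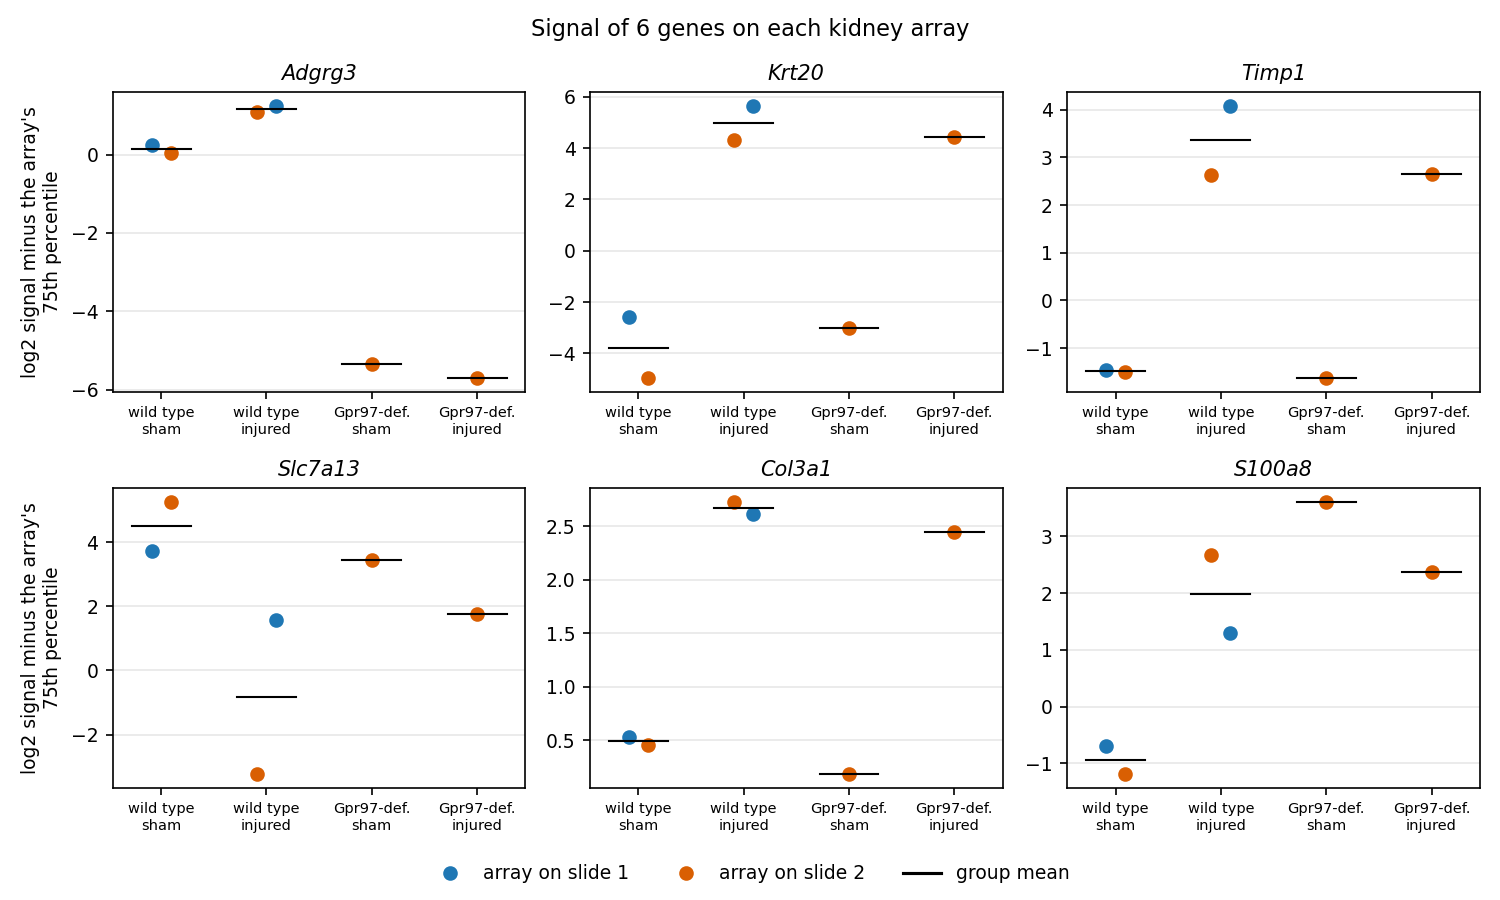
Signal of 6 genes on each array, as log2 signal minus the 75th percentile of the array (vertical axis), by group; each point is 1 array, blue for slide 1 and orange for slide 2, and each line is the group mean. Adgrg3 lies between 0.05 and 1.25 on the 4 wild-type arrays and at -5.34 and -5.71 on the Gpr97-deficient arrays, and Krt20 lies at 4.31 or above on the 3 injured arrays and at -2.58 or below on the 3 sham arrays.

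The comparison of injured with sham kidneys in wild-type mice showed a shift of the tubular injury genes. All 26 members were higher after injury, with a median of 2.0 (camera adjusted p 1.59e-20), and they rose together by this test. The adjusted p was 0.556 with an estimated correlation, and the medians within the slides were 2.57 on slide 1 and 1.64 on slide 2. Krt20, a keratin of simple epithelia, was 8.75 higher (SE 0.98). Sprr2f, a small proline-rich protein of stressed epithelia, was at least 87.5-fold higher, Timp1, an inhibitor of metalloproteinases, 4.84 higher (SE 0.56), and Sox9, a transcription factor of dividing tubule cells, 3.67 higher (SE 0.91). Of these 26 genes 12 passed when adjusted over the list alone, and 0 when adjusted over all genes.

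Genes of the acute phase and the cytokine and immediate early groups also rose after injury in wild-type mice. In the acute phase group 10 of 10 members were higher, with a median of 1.78 (camera adjusted p 1.03e-09, and adjusted p = 0.556 with an estimated correlation), 1.35 on slide 1 and 2.37 on slide 2. Saa2 and Saa1, serum amyloid A genes, were 6.17 (SE 1.06) and 2.33 (SE 0.51) higher, Saa3 at least 17.2-fold higher, and the metallothionein Mt2 2.66 higher (SE 0.50); 6 members passed when adjusted over the list alone and 0 over all genes. Inflammatory cytokines, chemokines and adhesion molecules had a median of 1.25 with 23 of 25 members higher (adjusted p 1.03e-09, and adjusted p = 0.556 with an estimated correlation), 1.55 on slide 1 and 0.79 on slide 2. Il1rn, the interleukin-1 receptor antagonist, was at least 8.27-fold higher, and the neutrophil chemokine Cxcl1 was 4.49 higher (SE 1.14). Immediate early genes had a median of 1.31 with 16 of 17 higher (adjusted p 9.18e-08, and adjusted p = 0.600 with an estimated correlation), with Fosl1 at 3.86 (SE 1.05) and Egr2 at 3.09 (SE 1.13), and medians of 1.81 on slide 1 and 0.91 on slide 2. Complement and coagulation genes had a median of 0.64 with 13 of 22 higher (adjusted p 0.00319, and adjusted p = 0.556 with an estimated correlation). The 3 members that passed when adjusted over the list alone were the fibrinogen chains Fgb, Fgg and Fga, higher by 6.24 (SE 1.21), 4.78 (SE 0.79) and 4.48 (SE 0.85). The complement and coagulation call ended without wild-type sham array 1 (median 0.47, adjusted p 0.0970).

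Neutrophil markers and matrix genes rose in the same comparison. The neutrophil list had a median of 2.15 with 13 of 17 members higher (camera adjusted p 1.68e-08, and adjusted p = 0.556 with an estimated correlation), 1.54 on slide 1 and 2.96 on slide 2. Clec4d and Il1r2 were at least 10.2-fold and at least 3.18-fold higher, Retnlg 2.94 higher (SE 0.67) and S100a8, a calcium-binding protein of neutrophils, 2.93 higher (SE 0.56); 9 members passed when adjusted over the list alone. Red blood cell markers lay 3.65 above the wild-type sham mean on wild-type injured array 1 and at -0.63 on wild-type injured array 2. Fibroblast and matrix genes had a median of 0.84 with 16 of 20 higher (adjusted p 3.40e-07, and adjusted p = 0.556 with an estimated correlation), 0.77 on slide 1 and 0.94 on slide 2, and Col3a1, a fibrillar collagen chain, was 2.17 higher (SE 0.23), the 1 member that passed when adjusted over the list alone. Smaller shifts upward passed for NRF2 targets (median 0.42, Hmox1 at 2.50), p53 targets (0.32, Cdkn1a at 3.13), cell death genes (0.19, Mlkl at 1.71), the unfolded protein response (0.34, Atf3 at 1.86), glycolysis (0.23, Hk2 at 2.72), ribosomal proteins (0.22) and the cell cycle (0.29, Tpx2 at 1.33). With an estimated correlation the adjusted p of these 7 lists lay between 0.556 and 0.674. With normexp background correction, which moved the median of all genes by 0.31, the camera test turned downward for the NRF2 (median 0.056), unfolded protein (0.078), glycolysis (-0.12) and ribosomal (-0.14) lists. In the main processing the cell cycle median was 0.55 on slide 1 and -0.05 on slide 2. The cell cycle call ended without wild-type sham array 1 (-0.12) or either injured array (0.19 and 0.45), and the glycolysis call without wild-type injured array 1 (0.10) or sham array 2 (0.14). Without wild-type injured array 2 the NRF2 (0.11), p53 (0.019) and ribosomal (0.20) calls ended, without wild-type sham array 1 the NRF2 (0.47), ribosomal (0.18) and cell death (0.26) calls, and without wild-type sham array 2 the unfolded protein call (0.22). The cell death call also ended with slide as a block (adjusted p 0.068). With normexp the cell death, p53, cell cycle and complement and coagulation calls ended.

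Transport and respiratory genes of the tubule fell after injury in wild-type mice. Of the 39 proximal tubule genes 36 were lower, with a median of -0.98 (camera adjusted p 3.19e-11, and adjusted p = 0.569 with an estimated correlation), -1.12 on slide 1 and -0.69 on slide 2, and 0 passed when adjusted over the list alone. Slc7a13, an amino acid transporter of the proximal tubule, was at -5.32 (SE 1.77) and Acsm3, an acyl-CoA synthetase, at -4.27 (SE 2.04). On wild-type injured array 1, the array with Xist, these genes stood at -3.23 and -1.98, and on wild-type injured array 2 at 1.57 and 3.56. Slc7a13 changed by -2.2 on slide 1 and -8.5 on slide 2, and Acsm3 by -0.61 and -7.9. In the Gpr97-deficient pair they changed by -1.7 and 2.1. The larger part of both falls came from the array with Xist, where a difference in sex cannot be told apart from injury. The median of the proximal tubule genes was -1.27 without wild-type injured array 1 and -0.60 without wild-type injured array 2. Thick ascending limb and distal tubule genes had a median of -0.49 with 17 of 20 lower (adjusted p 0.00586, and adjusted p = 0.674 with an estimated correlation), with Egf at -2.86 (SE 1.20) and Pvalb at -2.65 (SE 2.12). Their median was -1.07 on slide 1 and -0.05 on slide 2, and 0.067 without wild-type injured array 2, where the call ended, as it did without wild-type sham array 2 (-0.56). Genes of the TCA cycle and respiratory chain had a median of -0.32 with 27 of 28 lower (adjusted p 0.00319, and adjusted p = 0.674 with an estimated correlation), -0.50 on slide 1 and -0.10 on slide 2, with Idh2 at -0.83 (SE 0.46) and Sdhb at -0.67 (SE 0.32), and the call ended without wild-type injured array 2 (-0.048) or sham array 2 (-0.20). T and NK cell markers had a median of -0.90 with 15 of 16 lower (adjusted p 0.00575, and adjusted p = 0.674 with an estimated correlation), with Nkg7 at -1.83 (SE 1.77). The T and NK median was 0.034 without wild-type sham array 2, -0.27 without wild-type injured array 2, neither past the test, and 0.65 with normexp.

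By single gene, limma called 0 of 19615 genes for injury in wild type (2 against 2 arrays), and 1249 genes had an unadjusted p under 0.05, 655 up and 594 down, against 981 expected by chance. The largest moderated t upward, not past the threshold, belonged to Chil3, a chitinase-like protein of myeloid cells (3.80, SE 0.29), Mmp7, a metalloproteinase (at least 14.5-fold), and Sprr2f. Downward they belonged to Chrdl1 (-2.78, SE 0.28), Dcst1 (-2.22, SE 0.24) and Slc22a28 (-3.0, SE 0.36). Without wild-type injured array 1 the count was 0, with 2203 genes at an unadjusted p under 0.05, and without wild-type sham array 2 it was 0 with 700. In the additive model of genotype and surgery, 3 injured against 3 sham arrays, 0 genes passed and 2408 had an unadjusted p under 0.05. In that model Sprr2f passed with slide as a block (adjusted p 0.00891), with quantile normalization (adjusted p 0.0356) and with the deposited values (adjusted p 0.0402). With a variance trend and robust prior 3 genes passed in it, Sprr2f, Col3a1 (adjusted p 0.0225 each) and Mmp7 (adjusted p 0.0361). Genes that differed at least 2-fold the same way in all 3 within-slide pairs of an injured and a sham array numbered 234 up and 149 down, against 3.47 and 4.43 if the pairs were independent. That expectation gives every gene the same share, though genes with a wide spread pass 2-fold more often in any pair. An excess over it does not by itself show a shared change. Across genes, which are not independent replicates, the wild-type pairs of slides 1 and 2 correlated with r = 0.32 (Spearman's rho 0.29).

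**Figure D3:**
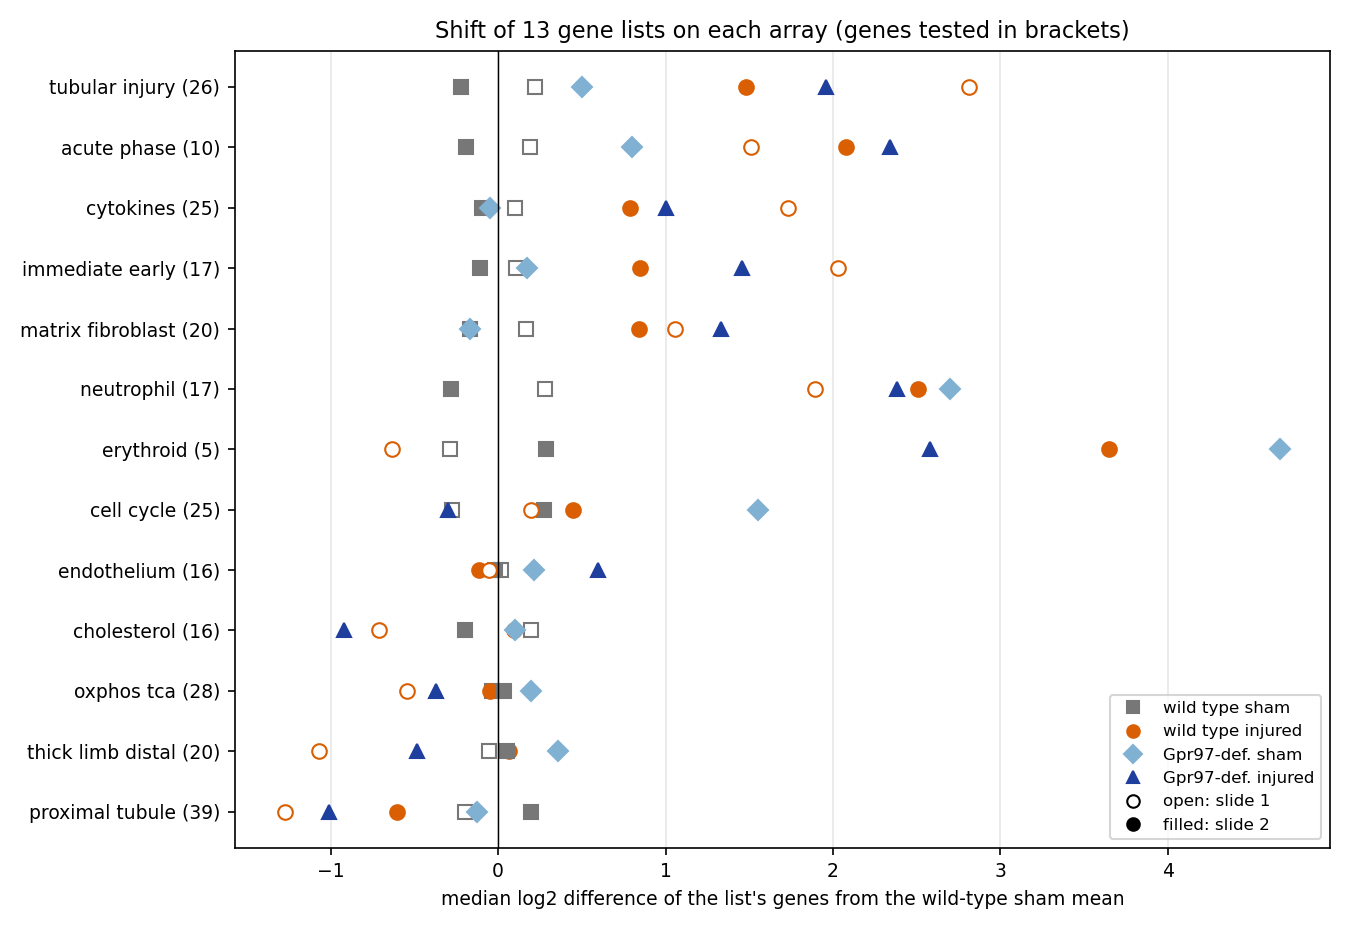
Median log2 difference of 13 gene lists from the wild-type sham mean (horizontal axis) on each of the 6 arrays; squares are wild-type sham, circles wild-type injured, diamonds Gpr97-deficient sham and triangles Gpr97-deficient injured, open for slide 1 and filled for slide 2. The tubular injury list lies at 1.48, 2.81 and 1.96 on the injured arrays, and the erythroid list at 3.65, 4.67 and 2.58 on 3 of the 4 arrays of slide 2.

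The comparison of the injured with the sham kidney of Gpr97-deficient mice, 1 array against 1 on slide 2, showed the tubular injury genes higher as well. Of 26 members 24 were higher, with a median of 1.78 (camera adjusted p 6.80e-18, and adjusted p = 0.376 with an estimated correlation), Sprr2f by at least 99.0-fold, Krt20 by 7.46 (SE 1.38) and Timp1 by 4.27 (SE 0.79). Matrix genes rose with a median of 1.23, 18 of 20 higher (adjusted p 2.72e-13, and adjusted p = 0.323 with an estimated correlation), Col3a1 by 2.26 (SE 0.33). Cytokines had a median of 1.02, immediate early genes 1.31, the acute phase group 1.37, complement and coagulation 0.79 and the unfolded protein response 0.71, each past the camera test with an adjusted p of 3.55e-06 or lower, and between 0.323 and 0.470 with an estimated correlation. Saa2 was at least 280-fold higher and Fgg, a fibrinogen chain, 4.83 higher (SE 1.11). Fatty acid oxidation genes had a median of 0.50 with 17 of 23 higher (adjusted p 6.16e-05, and adjusted p = 0.323 with an estimated correlation). NRF2 targets (0.45), p53 targets (0.46), glucocorticoid targets (0.85, Pdk4 at 3.06), adipocyte markers (1.05, Cidec at 4.01) and endothelial markers (0.29, Nos3 at 1.05) also passed upward, with an adjusted p between 0.376 and 0.568 with an estimated correlation. The glucocorticoid call ended with the mean of the probes. With slide as a block T and NK markers (median -0.59, 15 of 16 lower) also passed, downward, which they did not in the main fit.

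Cell cycle genes were lower on the Gpr97-deficient injured array than on the Gpr97-deficient sham array, 25 of 25 with a median of -2.41 (camera adjusted p 8.33e-21, and adjusted p = 0.323 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, was at least 10.9-fold lower and Rrm2, a subunit of ribonucleotide reductase, at -2.50 (SE 0.43). Red blood cell markers had a median of -2.15 with 5 of 5 lower (adjusted p 0.0242, and adjusted p = 0.578 with an estimated correlation), Alas2 at -2.52 (SE 2.94). Against the wild-type sham mean, the cell cycle genes lay at 1.55 on the Gpr97-deficient sham array and -0.30 on the injured one, and the red blood cell markers at 4.67 and 2.58. Cholesterol synthesis genes had a median of -1.18 with 16 of 16 lower (adjusted p 1.13e-10, and adjusted p = 0.462 with an estimated correlation), Insig1 at -2.28 (SE 1.07) and Cyp51 at -1.95 (SE 0.55). Thick limb and distal genes (median -0.78), proximal tubule genes (-0.70, Slc34a3 at -3.25 and Gatm at -2.78) and the respiratory chain group (-0.60, Idh2 at -1.09) fell too, with an adjusted p of 3.55e-05 or lower, and between 0.516 and 0.568 with an estimated correlation. Neutrophil markers did not pass as a list (median -0.26, adjusted p 0.157), with the granule proteins Camp at least 19.0-fold lower and Ltf at -3.68 (SE 0.73), and Clec4d 2.79 higher (SE 0.59). Limma called 0 genes in this comparison, and 537 had an unadjusted p under 0.05, fewer than the 981 expected by chance. Among the largest moderated t were those of Zcwpw2 (at least 8.58-fold higher), Mmp7 (at least 50.1-fold higher), Pbk (at least 38.1-fold lower), Cdk1 and Krtap19-5 (at least 6.04-fold lower), none past the threshold. The spread in this comparison comes from the wild-type arrays, like which the lone Gpr97-deficient arrays are assumed to vary.

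Genotype after injury compared the Gpr97-deficient injured array with the 2 wild-type injured arrays and bears on whether the receptor alters the injured kidney. Endothelial markers were higher in the Gpr97-deficient kidney, 16 of 16 with a median of 0.53 (camera adjusted p 4.01e-10, and adjusted p = 0.65 with an estimated correlation). The median was 0.61 with slide as a block, 0.54 within slide 2 and 0.52 against the wild-type array of slide 1; Nos3, the endothelial nitric oxide synthase, was at 0.80 (SE 0.36) and Vwf, von Willebrand factor, at 0.79 (SE 0.53). Cholesterol synthesis genes were lower, 16 of 16 with a median of -0.81 (adjusted p 2.46e-08, and adjusted p = 0.65 with an estimated correlation), -1.15 within slide 2 and -0.53 against slide 1, with Insig1, a brake on sterol synthesis, at -1.70 (SE 0.93). Cell cycle genes were lower, 23 of 25 with a median of -0.51 (adjusted p 9.35e-06, and adjusted p = 0.65 with an estimated correlation), -0.56 within slide 2 and -0.62 against slide 1. Fatty acid oxidation genes were higher, 20 of 23 with a median of 0.29 (adjusted p 9.87e-05, and adjusted p = 0.65 with an estimated correlation), 0.06 within slide 2 and 0.48 against slide 1, with Acot1, an acyl-CoA thioesterase, at 1.07 (SE 0.39).

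The tubular injury genes gave no shift by genotype after injury: the median was 0.03 with 14 of 26 higher (camera adjusted p 0.628), Lcn2 at 1.14 (SE 2.08) and Sprr1a at -1.75 (SE 2.0). Their median was 0.50 within slide 2 and -0.68 against the wild-type array of slide 1, and with slide as a block it was 0.41 (adjusted p 0.000855). Another 5 lists passed upward, and with an estimated correlation their adjusted p lay between 0.65 and 0.727. They were the acute phase group (0.63, Lbp at 1.16), matrix genes (0.37, Postn at 1.22), adipocyte markers (0.94, Fabp4 at 1.29), glucocorticoid targets (0.88, with Pdk4, a kinase that restrains pyruvate oxidation, at 2.64 and Fkbp5 at 1.45) and macrophage markers (0.52, Cd163 at 1.03). The glucocorticoid median was 0.26 without wild-type injured array 2, 1.56 without array 1 and 0.38 with slide as a block, and the macrophage median 0.24 and 0.82 without these arrays. The macrophage call ended with slide as a block (median 0.09, adjusted p 0.167). The adipocyte call ended with normexp and the glucocorticoid call with the mean of the probes. With that block 8 other lists passed, among them T and NK (-1.05, adjusted p 9.36e-05), immediate early (0.59, 0.00212) and respiratory chain genes (-0.27, 0.000883). The T and NK median was -0.61 against wild-type injured array 1 and 0.21 against wild-type injured array 2. Without wild-type injured array 1, the array with Xist, the acute phase, matrix and adipocyte lists no longer passed (0.86, 0.26 and 0.25). Without wild-type injured array 2 their medians were 0.32, 0.41 and 1.11. Sema3a, the secreted semaphorin, was at 0.32 (SE 1.43), its receptor chain Nrp1 at 0.67 (SE 0.32), and Plxna1, Plxna2, Plxna3 and Plxna4 at -0.25, 0.01, -0.04 and -0.09, none past the threshold; Sema3a, Plxna2, Plxna3 and Plxna4 changed sign in at least 1 alternative. Limma called 0 genes, and 281 had an unadjusted p under 0.05 against 981 expected by chance (734 without wild-type injured array 1 and 483 without array 2); with a variance trend and robust prior 1 gene passed, Adgrg3. Apart from Adgrg3, the largest moderated t belonged to Klrb1b (at least 6.90-fold higher), Vmn1r54 (at least 8.57-fold higher), Tagln3 (2.77, SE 0.37), Krtap19-5 (at least 8.92-fold lower) and Tex48 (at least 5.39-fold lower). The lists that passed numbered 9, and 16 without wild-type injured array 1, 23 without wild-type injured array 2 and 16 with slide as a block.

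Genotype after sham surgery compared the Gpr97-deficient sham array with the 2 wild-type sham arrays, and blood cell and cell cycle genes stood apart. Red blood cell markers were higher, 5 of 5 with a median of 4.67 (camera adjusted p 1.13e-05, and adjusted p = 0.553 with an estimated correlation), 4.38 within slide 2, with Alas2, the erythroid haem synthesis enzyme, at 5.0 (SE 2.55) and the globin gene Hbb-bt at 4.73 (SE 2.01). Neutrophil markers were higher, 14 of 17 with a median of 2.70 (adjusted p 9.66e-22, and adjusted p = 0.553 with an estimated correlation), 3.54 within slide 2. Their median ran from 0.45 with normexp to 4.07 with probes above background on all 6 arrays. Ngp, a neutrophil granule protein, was at least 14.3-fold higher, and S100a8, S100a9 and Retnlg were at 4.56 (SE 0.68), 4.34 (SE 0.64) and 3.80 (SE 0.83); 12 members passed when adjusted over the list alone and 0 over all genes. Cell cycle genes were higher, 24 of 25 with a median of 1.55 (adjusted p 1.11e-25, and adjusted p = 0.553 with an estimated correlation), 1.42 within slide 2. The mitotic genes Cdk1, Birc5, Aurka and Cdc20 were at 3.06 (SE 0.42), 2.76 (SE 0.66), 2.55 (SE 0.52) and 2.42 (SE 0.53), and 7 members passed when adjusted over the list alone. The tubular injury group had a median of 0.50 with 19 of 26 higher (adjusted p 0.0181, and adjusted p = 0.79 with an estimated correlation), and the acute phase group 0.80 with 7 of 10 higher (adjusted p 0.00475, and adjusted p = 0.553 with an estimated correlation), with Hp, haptoglobin, at 2.82 (SE 0.99).

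Smaller shifts by genotype after sham surgery passed upward for macrophage (0.64), collecting duct (0.44), thick limb and distal (0.36), ribosomal (0.29), p53 target (0.22), endothelial (0.21), respiratory chain (0.20), cell death (0.19) and podocyte genes (0.17). Heat shock genes (-0.32, with 10 of 13 lower and Dnaja1 at -1.04) and fatty acid oxidation genes (-0.02, with 13 of 23 lower) passed downward, and with an estimated correlation the adjusted p of these 11 lists lay between 0.553 and 0.79. With slide as a block the macrophage (0.23, adjusted p 0.109), collecting duct (-0.05, adjusted p 0.574), thick limb (0.04, adjusted p 0.574), respiratory chain (0.05, adjusted p 0.671), cell death (0.25, adjusted p 0.05004) and heat shock (-0.32, adjusted p 0.214) lists no longer passed. With that block T and NK (-0.99, adjusted p 3.77e-08), proximal tubule (-0.39, 0.000176) and immediate early genes (0.45, 0.00147) passed as well. With the deposited values the ribosomal (0.052, adjusted p 0.634), respiratory chain, thick limb, p53 and tubular injury calls ended. Quantile normalization ended the same 5 calls. The T and NK median was -1.285 against wild-type sham array 2 and 0.50 against wild-type sham array 1, and these 2 arrays differed by a median of 1.66 in this list. The mean of the probes ended the podocyte and fatty acid oxidation calls, no filter on dim probes the heat shock and fatty acid oxidation calls, and probes above background on all 6 arrays the p53 call. Limma called 0 genes, with 419 at an unadjusted p under 0.05, fewer than the 981 expected by chance. The largest moderated t, not past the threshold, belonged to Chil3 (3.86, SE 0.36), Camp (3.55, SE 0.46), Klrb1b (at least 1.58-fold higher), Adgrg3, Chrdl1 (-3.58, SE 0.34) and Sec14l3 (-3.79, SE 0.45). The lists that passed numbered 16, and 10 without either wild-type sham array. Without wild-type sham array 1 the macrophage (0.073), cell death (0.068), respiratory chain (0.11) and thick limb (0.26) calls ended, and without wild-type sham array 2 the collecting duct (0.36), acute phase (0.67) and tubular injury (0.20) calls. Without either, the endothelial (0.24 and 0.27), podocyte (0.30 and 0.20), heat shock (-0.22 and -0.24), p53 (0.20 and 0.12) and fatty acid oxidation (-0.30 and -0.25) calls ended, and the p53 and fatty acid oxidation calls ended without either injured array as well. In the latter case their medians stayed at 0.22 and -0.025, since injured arrays enter this comparison only through the shared spread. Leaving out a wild-type array lowers the residual degrees of freedom, so a call can end without a smaller shift.

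The interaction asked whether the change with injury differs between genotypes, and the blood and cell cycle genes set apart the responses. Cell cycle genes had a median difference of -2.28 with 25 of 25 lower (camera adjusted p 2.85e-32, and adjusted p = 0.483 with an estimated correlation). The list lay 1.55 above the wild-type sham mean on the Gpr97-deficient sham array. Neutrophil markers had a median of -2.41 with 16 of 17 lower (adjusted p 2.13e-17, and adjusted p = 0.483 with an estimated correlation), and red blood cell markers -3.49 with 5 of 5 lower (adjusted p 0.0009, and adjusted p = 0.837 with an estimated correlation). The red blood cell median was -1.34 without wild-type injured array 1 and -5.63 without array 2. Cholesterol synthesis genes had a median of -0.74 with 15 of 16 lower, and fatty acid oxidation genes 0.49 with 18 of 23 higher. Adipocyte markers (1.12), endothelial markers (0.38) and matrix genes (0.36) were higher, and ribosomal (-0.32), glycolysis (-0.30) and respiratory chain genes (-0.28) lower. With an estimated correlation the adjusted p of these 8 lists lay between 0.483 and 0.888. Ribosomal, glycolysis and respiratory chain genes turned upward with normexp. Their calls ended with quantile normalization and with the deposited values. The tubular injury genes had a median of -0.23 (adjusted p 0.138) and the proximal tubule genes 0.07 (adjusted p 0.0523), neither past the test. Limma called 0 genes and 292 had an unadjusted p under 0.05, fewer than the 981 expected by chance. Chrdl1, Xlr3c (3.21, SE 0.39), Cdc6, Pbk and Krtap19-5 were among the genes with the largest moderated t, none past the threshold. Without wild-type injured array 2 the lists that passed numbered 19, against 11 with all arrays. Without wild-type injured array 1 the cholesterol (-0.45, adjusted p 0.0501), endothelial (0.32), matrix (0.47), glycolysis (-0.080) and respiratory chain (-0.030) calls ended. Without wild-type sham array 1 the matrix (0.12), respiratory chain (-0.25) and ribosomal (-0.32) calls ended, and without wild-type sham array 2 the endothelial (0.36) and glycolysis (-0.22) calls. The glycolysis call also ended with slide as a block (adjusted p 0.0642) and without a filter, and with that block unfolded protein (0.37, 0.0182) and clock genes (0.46, 0.0214) passed.

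Over both surgeries, 2 Gpr97-deficient against 4 wild-type arrays, endothelial markers were higher in all 16 members with a median of 0.36 (camera adjusted p 2.88e-08, and adjusted p = 0.518 with an estimated correlation), 0.41 with slide as a block, with Vwf at 0.87 (SE 0.33) and Cldn5, a tight junction protein of endothelium, at 0.63 (SE 0.28). The endothelial median was 0.21 without the Gpr97-deficient injured array and 0.53 without the Gpr97-deficient sham array. With 1 Gpr97-deficient array left out, this comparison equals genotype after sham surgery or after injury as given above. Such results repeat those comparisons and are no further check. Neutrophil (1.55), red blood cell (2.94) and cell cycle (0.46) genes passed upward, and without the Gpr97-deficient sham array the neutrophil (0.35, adjusted p 0.0968) and red blood cell (1.23, adjusted p 0.481) calls ended and the cell cycle median was -0.51. With normexp the neutrophil call ended as well (-0.065, adjusted p 0.178). Macrophage (0.58), acute phase (0.63), glucocorticoid (0.55, Pdk4 at 2.10), collecting duct (0.38), p53 target (0.24), thick limb (0.22), cell death (0.20), interferon (0.16), ribosomal (0.14) and podocyte genes (0.13) passed upward, and heat shock (-0.31) and cholesterol synthesis genes (-0.28, Idi1 at -0.99) downward. The adjusted p of these 15 lists lay between 0.518 and 0.864 with an estimated correlation. Without the Gpr97-deficient sham array the cell death, collecting duct, heat shock, interferon, p53, podocyte, ribosomal (-0.020) and thick limb calls ended too. Without the Gpr97-deficient injured array the cholesterol (0.10), glucocorticoid (0.30) and interferon (0.12) calls ended. The podocyte, thick limb, ribosomal, interferon, cholesterol, cell death, p53 and collecting duct calls each ended without at least 1 wild-type array, with cholesterol at -0.13 and p53 at 0.059 without wild-type injured array 1, and thick limb at -0.030 without wild-type injured array 2. Red blood cell (adjusted p 0.0603), collecting duct (0.737), thick limb (0.552), interferon (0.67, median -0.035), podocyte (0.108) and heat shock (0.169) lists no longer passed with slide as a block. The macrophage list still passed with it, at a median of 0.23 (camera adjusted p 0.0416). Quantile normalization and the deposited values each ended the interferon, podocyte, ribosomal and thick limb calls. Normexp and no filter each ended the cholesterol and heat shock calls, and the mean of the probes the podocyte call. With slide as a block, 7 other lists passed, among them T and NK (median -0.90, adjusted p 2.60e-08), tubular injury (0.62, 4.23e-07), immediate early (0.62, 7.53e-05) and proximal tubule genes (-0.33, 0.000381). The T and NK median was -0.12 without the block, and after each surgery its sign depended on the wild-type array used. Limma called 0 genes, with 632 at an unadjusted p under 0.05, fewer than the 981 expected by chance. It called 1 gene with a variance trend and robust prior, Adgrg3. Klrb1b, Ocel1 (1.73, SE 0.25), Itga10, Lrrc46 (-0.79, SE 0.17) and Bdnf (-0.84, SE 0.19) followed Adgrg3 in moderated t, none past the threshold. Of the genotype pairs of slide 2, 83 genes were at least 2-fold higher and 215 at least 2-fold lower in both, against 21.7 and 35.4 if the pairs were independent, and across genes the pairs correlated with r = 0.02 (Spearman's rho 0.01). That expectation gives every gene the same share. With pairs that hardly correlated, the excess over it does not show a shared genotype effect.

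The size of the injury response was read on genes picked at 2-fold on 1 pair of wild-type arrays and read on the other pair and on the Gpr97-deficient arrays. For genes picked on the slide 2 pair, the median change in the picked direction was 0.52 in the wild-type pair of slide 1 and 0.38 in the Gpr97-deficient pair. For genes picked on the slide 1 pair, it was 0.39 in the wild-type pair of slide 2 and 0.66 in the Gpr97-deficient pair. Over the 4 choices of picking arrays the Gpr97-deficient minus wild-type difference was 0.33 ± 0.35 (SD over the choices), from -0.14 to 0.68. The differences of 0.68 and 0.50 came from picks that crossed the slides, where the wild-type medians were -0.53 and -0.03. This difference was not tested.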

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

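The tests on the dim array, the swap, the spleen list and on Gpr97 deficiency in both surgeries were chosen only after the result was seen, as were the slide block for gene lists and the leaving out of Gpr97-deficient arrays.

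The first set of results differed between the genotypes in the change with injury, by the camera test of the interaction. The median difference, Gpr97-deficient minus wild type, was -3.49 for red blood cell markers, -2.41 for neutrophil markers and -2.28 for cell cycle genes. It was -0.74 for cholesterol synthesis, -0.32 for ribosomal proteins, -0.30 for glycolysis and -0.28 for the respiratory chain. It was 1.12 for adipocyte markers, 0.49 for fatty acid oxidation, 0.38 for endothelial markers and 0.36 for matrix genes. None of these 11 lists passed with an estimated correlation (lowest adjusted p 0.483). That setting also called 0 of the 3 lists shifted in the simulation, all by the same size. Other sizes were not simulated, so this failure cannot decide for or against a difference.

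The red blood cell, neutrophil and cell cycle lists were high on the Gpr97-deficient sham array, at 4.67, 2.70 and 1.55 above the wild-type sham mean, and the red blood cell list also lay at 3.65 on wild-type injured array 1 and 2.58 on the Gpr97-deficient injured array. Spleen tissue in the Gpr97-deficient sham sample is argued against by the B cell list, whose median was -0.27, for the 8 of 12 members tested. A B cell gene detected on that array alone would have been left out by the filter. Wild-type sham array 2 differed from array 1 by -0.52 in this list. An effect of Gpr97 deficiency in both surgeries on the cell cycle genes is argued against too, since after injury the Gpr97-deficient array was below both wild-type arrays, at -0.62 and -0.56 from them. Marrow-type blood cells cannot be told apart from other sources, since the median of red cell, granulocyte and platelet precursor genes, of which 22 of 32 were measured in these kidneys, was 0.72 with 18 of 22 higher, between the bounds set for and against. Its parts were 0.24 for erythroblast, 1.14 for granulocyte precursor and 0.82 for platelet genes, the last of which differed by 0.86 between the wild-type sham arrays. For the neutrophil genes, an effect of Gpr97 deficiency in both surgeries cannot be told apart from a trait of 1 sample, since after injury they were 0.67 and 0.034 above the wild-type arrays.

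On wild-type injured array 1 the 4 Y-linked genes were not well above background, and Xist, whose probes are in none of the gene comparisons, was at 4.10, well above background on that array alone. A female animal may account for the missing Y-linked signal, since Xist, a gene of another chromosome, was 9.48 above the highest other array. A dim array is argued against by the share of probes well above background, -0.763 percentage points from the lowest other array of its slide. In the test for an animal of another strain, 7 probes were far below all other arrays, against 8 on the highest other array. How many such probes another strain would give is not known here, so this test cannot decide. A swap with an array of another group of the series is argued against by Adgrg3, which stood 6.44 above the highest Gpr97-deficient array, and Krt20, at 4.31 against -2.58 or below on the sham arrays. An exchange with a sample from outside the series stays open, and no biological explanation beyond sex was tested.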

How the results depend on the processing

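The slide block for gene lists and named genes, the additive model with slide as a block, outlier spots kept for lists and the leaving out of Gpr97-deficient arrays were chosen only after the result was seen. No paired analysis was possible by replicate number because these numbers were given in accession order; the pairs used are those within a slide. In the 6 comparisons limma called 0 genes under the alternatives, except 1 each for genotype after injury and over both surgeries with a variance trend and robust prior. With slide as a block, genes at an unadjusted p under 0.05 went from 1249 to 1975 for injury in wild type. For injury in Gpr97-deficient mice they went from 537 to 1061, and for genotype after injury from 281 to 665. The counts went from 419 to 791 after sham, 292 to 564 for the interaction and 632 to 920 over both surgeries. By chance 981 were expected in each. The additive model of 3 injured against 3 sham arrays of both genotypes called 0 genes, 1 with slide as a block, 1 with quantile normalization, 1 with the deposited values and 3 with a variance trend and robust prior. With an estimated correlation 0 lists passed in all 6 comparisons. That setting also called 0 of the 3 lists shifted in the simulation, all by the same size. Other sizes were not simulated, so it cannot decide for or against the list results. Normexp moved the median of all genes by 0.31 for injury in wild type, -0.23 for genotype after injury and -0.22 for the interaction, so list directions there are relative to that shift. For genotype after injury 26 lists passed with normexp, 18 without a filter and 16 with slide as a block, and leaving out 1 array gave 11 to 23. The ranges were 10 to 16 after sham surgery, 13 to 19 for the interaction and 9 to 18 over both surgeries, lowest without the Gpr97-deficient sham array. Without the Gpr97-deficient sham array the comparison over both surgeries equals genotype after injury, so that lowest count repeats it. The Gpr97-deficient minus wild-type difference in the size of the injury response was -0.14 with normexp, and 0.68 and -0.14 when picked on wild-type injured array 1 with sham array 1 or 2. The cause was not tested for any of these or the following reversals.

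With normexp the direction of the camera test turned for injury in wild type in the unfolded protein (0.078), NRF2 (0.056), glycolysis (-0.12), ribosomal (-0.14) and T and NK (0.65) lists, for the interaction in glycolysis (0.012), respiratory chain (0.071) and ribosomal (0.055) lists, and over both surgeries in heat shock (-0.13). The deposited values turned the respiratory chain after sham surgery (0.050) and ribosomal genes over both surgeries (-0.023), and slide as a block the thick limb list over both surgeries (-0.10). Leaving out 1 array turned 6 lists. They were cell cycle over both surgeries (-0.51 to 1.55), cell cycle for injury in wild type (-0.12 to 0.61), cholesterol over both surgeries (-0.81 to 0.10), ribosomal over both surgeries (-0.020 to 0.29), T and NK (-1.82 to 0.034) and thick limb for injury in wild type (-1.07 to 0.067). Those over both surgeries turned without a Gpr97-deficient array, where the comparison equals that of the other surgery alone.

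Of the named genes, Sema3a and the plexins, none past the threshold, turned most often. Normexp turned Plxna1, interaction of genotype and injury (0.00027), Plxna3 for injury in Gpr97-deficient mice (-0.011) and for the interaction (-0.91), Plxna4 for injury in wild type (0.39) and Sema3a after injury (-1.14), for injury in wild type (0.60) and for the interaction (-0.71). Quantile normalization turned Plxna3 after injury (0.080) and over both surgeries (0.014). The deposited values turned Plxna3 after injury (0.082) and over both surgeries (0.014). Slide as a block turned Plxna1 after sham (0.032), Plxna3 after injury (0.21), after sham (0.085) and over both surgeries (0.15) and Sema3a after sham (0.26) and over both surgeries (0.81). The mean of the probes turned Plxna3 for the interaction (-0.024), Plxna4 after sham (0.37) and for injury in wild type (0.080) and Sema3a after injury (-1.65), for injury in wild type (0.50) and for the interaction (-0.67). Leaving out 1 array gave Plxna1 a range of -0.34 to 0.079 for the interaction. With 1 array left out, Plxna2 after injury was -0.19 to 0.22, and Plxna2, interaction of genotype and injury, -0.40 to 0.00052. The ranges of Plxna3 were -0.17 to 0.082 after injury, -0.57 to 0.22 after sham, -0.27 to 0.068 over both surgeries, -0.33 to 0.46 for injury in wild type and -0.26 to 0.52 for the interaction. The ranges of Plxna4 were -0.32 to 0.14 after injury, -0.22 to 0.13 after sham, -0.16 to 0.035 over both surgeries and -0.28 to 0.18 for the interaction. Sema3a had ranges of -1.25 to 1.88 after injury, -0.98 to 0.36 over both surgeries, -2.80 to 0.33 for injury in wild type and -0.46 to 2.67 for the interaction.

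Of 89 list results that passed, 77 kept direction and side of the threshold with quantile normalization, 77 with the deposited values (which are nearly the quantile-normalized ones), 73 with normexp and 74 with slide as a block. They numbered 84 without a filter, 84 with the mean of the probes, 88 with probes above background on all 6 arrays and 89 with outlier spots kept. Without wild-type sham array 1 or 2 they numbered 68 and 71, and without wild-type injured array 1 or 2 they numbered 72 and 77. Signal over background limits what the dim probes can show, since 63.0% to 71.1% of the probes of an array were well above it.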

Other observations

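The readings of single arrays given here for the clock genes and Sema3a were chosen only after the result was seen.

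Lists fixed beforehand that passed the camera test in none of the 6 comparisons without slide as a block are given here as values. The Sema3A axis of 6 genes had a median of 0.15 for injury in wild-type mice (adjusted p 0.411), 0.16 in Gpr97-deficient mice (0.192) and -0.015 for genotype after injury (0.628). The brightest of the 4 probes of Sema3a was well above background on 5 of 6 arrays, at -2.86 and -3.90 on the wild-type sham arrays, -3.05 on wild-type injured array 2 and -4.16 and -4.30 on the Gpr97-deficient arrays. On wild-type injured array 1 it stood at -6.18, not well above background, while a second probe was at -1.84, well above background on that array alone, so the probes of Sema3a disagree there. Other semaphorins, plexins and neuropilins had a median of 0.057 for injury in wild-type mice with 14 of 24 higher, Sema6b at 1.44 (SE 0.27) and Sema7a at 1.13 (SE 0.34). In the additive model Sema6b was 1.28 higher after injury (SE 0.20), which passed when adjusted over the list alone (limma adjusted p 0.0359) and not over all genes (0.258).

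Genes beside Adgrg3 on its chromosome had a median of 0.058 over both surgeries with 13 of 23 higher (adjusted p 0.167). Ccl17, a chemokine gene of this group, was 1.59 higher in Gpr97-deficient kidneys (SE 0.26), the 1 member that passed when adjusted over the list alone (limma adjusted p 0.0390; 0.994 over all genes). It was at 1.23 after sham surgery and 1.94 after injury.

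Circadian clock genes had a median of -0.86 for injury in wild-type mice with 10 of 15 lower (adjusted p 0.156), -1.27 on slide 1 and -0.12 on slide 2, with Ciart at -2.58 (SE 0.94) and Dbp at -2.01 (SE 0.82). Wild-type injured array 2 lay at -1.26 and the other 5 arrays between -0.28 and 0.15 of the wild-type sham mean. In the additive model Nr1d2 was at -1.04 (SE 0.17) and Nfil3 at 1.5 (SE 0.30), both past the threshold adjusted over the list alone (limma adjusted p 0.0223 and 0.0317) and neither over all genes. Hypoxia targets had a median of 0.23 (adjusted p 0.48), B cell markers -0.60 (0.271), adrenal genes 0.086 (0.931) and housekeeping genes -0.027 (0.893) for injury in wild-type mice. The list of 4 Y-linked genes had a median of -3.37 there (adjusted p 0.0672), -0.19 on slide 1 and -6.61 on slide 2, the slide with wild-type injured array 1. With slide as a block this list passed (camera adjusted p 0.0417).

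Of the 10 splits of the 6 arrays into 3 against 3, fitted without genotype, the real split of injured and sham arrays gave 2779 genes at an unadjusted p under 0.05, a number that 1 split, the real one, reached. The highest of the other splits gave 1719, and it grouped wild-type sham array 1, wild-type injured array 2 and the Gpr97-deficient injured array, with both arrays of slide 1. These splits are too few for a share under 0.05.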
